A study of Homo sapiens with 8 samples.

How the data were processed

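Total RNA from HT29 monolayers, either at 0 h or after 1, 2 or 4 h of contact with B. bifidum PRL2010, was extracted on spin columns with DNase digestion, reverse transcribed, amplified and labelled with Cy5 for 1-colour CombiMatrix arrays, per the labels' protocols. The deposited values are linear probe intensities in a single table of 62192 rows and 8 arrays. Scanner software, background correction and normalization are not given in the sources used here. From the values, 7 of the 8 columns hold the same sorted intensities, which is what quantile normalization between arrays leaves; the column of 4 h replicate 2 has a slightly different distribution. The highest intensity is 65535.

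Groups and replicate numbers were taken from the labels, with 2 arrays per group. The values were taken as already normalized and were only converted to log2, with intensities of 0 (12 spots on 7 arrays and 5 on 4 h replicate 2) set to the lowest positive intensity, 16.15. The 114 control spots, 59 negative controls and 55 others, were left out. Each human probe ID carries a RefSeq accession, which was matched without its version to gene symbols of the GRCh38.p14 annotation, used for names only: 21450 of 24197 accessions and 56283 of 62078 human probes (90.7%) matched 1 symbol, and the remaining 5795 probes were left out of the gene fit. Probes of a gene were averaged on the log2 scale (median 3 probes per gene; 707 genes have 1 probe), no dim gene was removed, and 18321 genes were tested. For part of the named genes whose probes disagreed, the number of probes that moved by more than 1 log2 is given. Named genes without that number may also rest on 1 such probe, as KRT20 and CALR did for at least 1 time. No detection call comes with the values, so the 95th percentile of the negative control spots describes the background; a change from a 0 h level below it is measured against background.

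Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group over all 8 arrays, 4 residual and 5.1 prior degrees of freedom, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The comparisons were 1, 2 and 4 h against 0 h, the mean of these times against 0 h, and 4 h against 1 h. 25 gene lists with 802 entries, of which 787 were measured, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists and the 3 times against 0 h together, with an estimated correlation and fry as alternatives. Under the variance prior with trend and robust, lists used only camera's trend setting. The lists were NF-kB-driven cytokines and chemokines, NF-kB pathway, Toll-like and NOD-like receptor signalling, immediate early genes, heat shock proteins, unfolded protein and integrated stress response, tight junction, adherens junction and desmosome, mucins and goblet cell products, antimicrobial proteins, interferon-stimulated genes, antigen presentation, hypoxia and glycolysis, NRF2 and oxidative stress, metallothioneins, cholesterol synthesis and uptake, enterocyte differentiation, proliferation, apoptosis and p53 targets, cytosolic ribosomal proteins, oxidative phosphorylation, reference genes, leukocyte markers, fibroblast and endothelial markers, and genes of unrelated tissues. Comparisons, tests, lists and the rule for named genes were fixed before the data were examined. Per comparison against 0 h the rule takes, among genes past the threshold whose arrays do not overlap those at 0 h, the 10 largest rises and the 10 largest falls (all that pass where fewer do), bare locus names last; it adds from each list the 4 members with the smallest p at 4 h and any member past the threshold adjusted over the list alone.

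Separation of a list from genes of unrelated tissues was computed within each array as the area under the curve over genes, with 95% intervals from 2000 bootstrap resamples of genes, and compared between 0 h and inoculated arrays by an exact permutation test over 28 splits. Correlations of comparisons with shared 0 h arrays were set beside 20 simulated data sets with no effect. The per-gene test was tested on simulated data for 4 h against 0 h with 18321 genes, 200 of them changed: 90% of changes of 1 log2 and 100% of changes of 2 log2 were recovered, with 11 false calls. Both simulations drew each gene on each array independently with the gene's moderated SD, without effects shared across an array. Their rates therefore need not hold for the arrays of this study. Alternatives were another normalization, an offset of 50, a filter on dim genes, a fit per probe, the groups in the fit, the variance prior, a block for the replicate number, other thresholds and leaving out each array. Zeros as missing, probes whose IDs end in S, the median of probes, the omission of 2 arrays that stand apart, comparisons of 4 h with 2 h and of 2 h with 1 h, and list tests between inoculated groups were added after seeing the data. The arrays give no count behind an intensity, so depth is not defined; the 2 replicates per group limit the precision. Figures were drawn with matplotlib 3.10.9.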

Results

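Gene expression was measured in HT29 cells, an established human colorectal adenocarcinoma line that forms epithelial monolayers, while they were in contact with Bifidobacterium bifidum PRL2010, a gut bacterium. The 8 arrays fall into 4 groups of 2 replicates: a 0 h control and monolayers sampled after 1, 2 and 4 h of contact. The question set by the design is how the transcript levels of the epithelial cells differ over the first hours with the bacterium. Each array gave a linear intensity for 62078 human probes, of which 56283 were matched to 18321 genes. Median intensity was 352.48 on 7 arrays and 344.88 on the array of 4 h replicate 2. Only 0 h arrays serve as control, so time in the assay and contact with the bacterium are not separated. Nothing in the labels says that the replicates came from separate cultures. The p-values therefore measure the spread between these arrays, which may be technical, and the number of arrays limits the precision.

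How well each array ranked abundant human transcripts differed between the 0 h and the inoculated arrays. Genes of cytosolic ribosomal proteins, which every dividing cell transcribes, were set against genes of unrelated tissues such as retina, heart and testis. Separation is the probability that a gene of the first list is brighter on an array than one of the second, with 0.5 for no separation. It was 0.488 ± 0.0297 (SD, n = 2) at 0 h and 0.793 ± 0.0553 (SD, n = 6) on the inoculated arrays, which ranged from 0.732 to 0.884 (two-sided exact permutation test over 28 splits, p = 0.0357, the smallest these splits can give). For reference genes the separation was 0.412 ± 0.017 (SD, n = 2) at 0 h and 0.657 ± 0.0676 (SD, n = 6) afterwards, with the same exact permutation p of 0.0357. Genes of oxidative phosphorylation lay at 0.448 ± 0.0686 (SD, n = 2) and 0.549 ± 0.0726 (SD, n = 6; exact permutation p = 0.143). Enterocyte genes lay at 0.432 ± 0.00424 (SD, n = 2) and 0.53 ± 0.0783 (SD, n = 6; exact permutation p = 0.25).

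**Figure D1:**
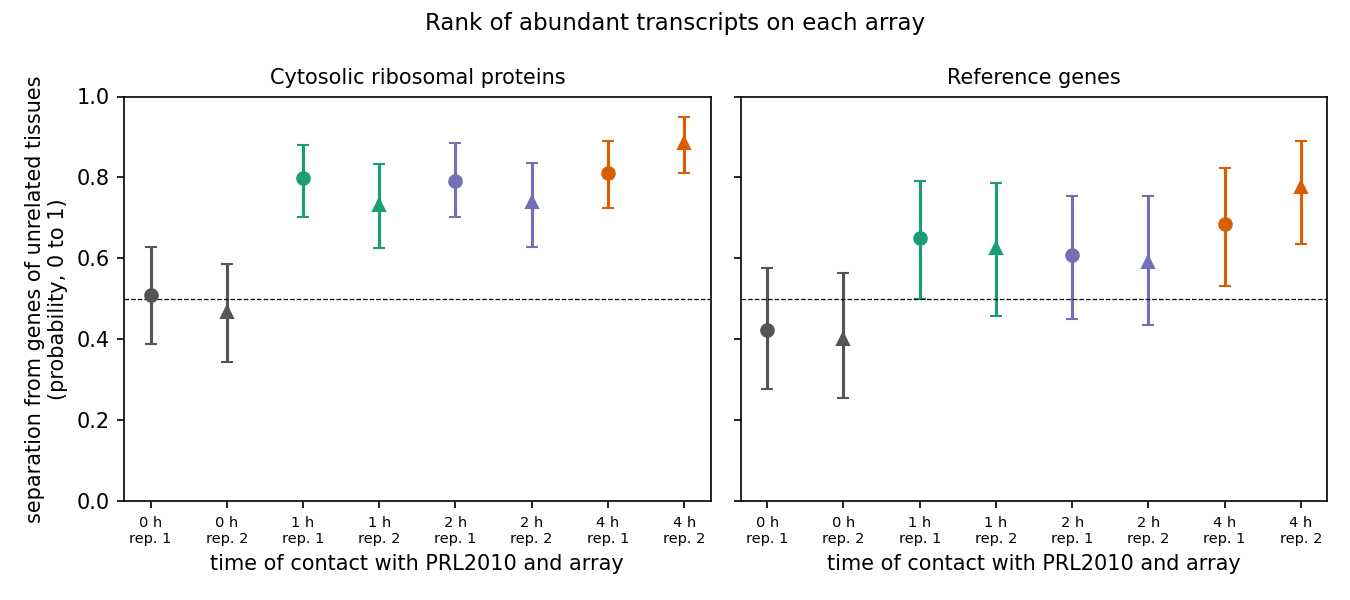
Separation of cytosolic ribosomal protein genes (left) and reference genes (right) from genes of unrelated tissues, on a scale of 0 to 1, for each of the 8 arrays; bars are 95% bootstrap intervals over genes, circles replicate 1, triangles replicate 2, and the dashed line is no separation. For ribosomal protein genes both 0 h arrays lie at 0.509 or below and all 6 inoculated arrays at 0.732 or above.

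After 1 h the genes with the largest rises included SCD, B2M and ACTB, the last of them a reference gene. Their 0 h means of 8.51, 8.54 and 8.47 lay within the background, so these changes are measured against background. SCD, the desaturase that makes monounsaturated fatty acids, rose from a log2 intensity of 8.51 ± 0.398 to 11.62 ± 0.48 (SD, n = 2 each), a change of 3.11 ± 0.282 (SE; adjusted p = 0.00236). B2M, the light chain of MHC class I, rose by 2.61 ± 0.203 and ACTB by 2.13 ± 0.261 (adjusted p = 0.00139 and 0.0111). All probes of these genes rose by more than 1 log2. ELFN1 (5.61 ± 0.811) and SLC13A1 (2.20 ± 0.188) also rose and have 1 probe each. In OR7A10 (3.67 ± 0.255), TPD52L2 (2.31 ± 0.134), EPPIN (2.18 ± 0.148) and ENC1 (2.20 ± 0.351) a single probe moved by more than 1 log2. The 7 genes that fell were led by SLC33A2 (-1.86 ± 0.238, 1 probe) and MYO1A, a myosin of the brush border (-1.61 ± 0.254, 2 of 3 probes over 1 log2). The others were FAM110D, TMEM14A, PLEKHO1, B4GALT3 and GMFG. Each of these others has 2 or 3 probes, of which 1 moved by more than 1 log2.

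Among the fixed gene lists at 1 h, epithelial and secretory genes supplied several of the calls. LYZ, the antibacterial enzyme lysozyme, rose by 1.99 ± 0.183 log2 and was the 1 of 34 antimicrobial genes called (1 adjusted over the list alone). KRT20, a keratin of differentiated colonic epithelium, rose by 1.21 ± 0.156 among 36 enterocyte genes, where MYO1A fell (1 higher and 1 lower adjusted over the list alone). FTH1, the ferritin heavy chain, rose by 1.27 ± 0.133, the 1 call of 25 oxidative stress genes (2 adjusted over the list alone). Of 30 mucin and goblet cell genes 2 rose, MUC17 by 1.71 ± 0.22 and AGR2, a disulfide isomerase needed for mucin folding, by 1.17 ± 0.159. Adjusted over the list alone 3 rose, and a single probe carried MUC17. EPCAM, an epithelial adhesion molecule, rose by 1.63 ± 0.241, the 1 call among 23 adherens junction and desmosome genes (3 adjusted over the list alone). INSIG1, which restrains sterol synthesis, rose by 1.13 ± 0.155, the 1 call among 25 cholesterol genes (3 adjusted over the list alone). Of 29 genes of the unfolded protein and stress response the chaperones CALR and HSP90B1 rose, by 1.07 and 0.96 (3 adjusted over the list alone). Of 31 hypoxia and glycolysis genes P4HA1, GAPDH and NDRG1 rose, by 1.42, 1.17 and 0.99 (4 adjusted over the list alone). Of 76 ribosomal protein genes 3 rose, RPL4, RPS26 and RPL3 (20 rose and 2 fell adjusted over the list alone). Of 20 reference genes 3 rose, among them ACTG1 and ACTB (4 adjusted over the list alone).

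Over all genes, limma called 77 higher and 7 lower at 1 h of 18321 tested, and 1414 genes had an unadjusted p under 0.05 where 916.05 are expected by chance. Of the 77 risen genes 75 had a 0 h mean below the 95th percentile of the negative control spots. Only 2245 and 1857 of 62078 human probes exceeded that level on the 0 h arrays. A 0 h level below it is therefore the rule on these arrays and does not set the called genes apart. Of the 77 called genes with 2 or more probes 49 had a single probe over 1 log2. Replicates differed most at 0 h and least at 4 h (SD of the log2 difference 0.371 and 0.224, with 0.305 at 1 h). The fit pools 1 variance per gene over all groups. The p-values at 1 h therefore rest in part on the narrower spread of later arrays and may be too small. The 84 calls became 162 (91 higher and 71 lower) without 0 h replicate 1, 42 without 1 h replicate 1, 40 without either 4 h array, 15 with only the compared groups in the fit, and 291 with 0 h replicate 1 and 1 h replicate 2 both left out, a setting chosen after seeing the data.

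At 2 h the lipid and secretory genes stood out. SCD rose by 4.03 ± 0.282 log2, from 8.51 ± 0.398, within the background, to 12.54 ± 0.419 (SD, n = 2 each; adjusted p = 0.000414), so the change is measured against background. B2M rose by 2.98 ± 0.203, TM4SF4, a tetraspanin-like membrane protein, by 2.72 ± 0.398, VMP1, an autophagy protein of the endoplasmic reticulum, by 2.66 ± 0.309 and LYZ by 2.35 ± 0.183. ELFN1 (4.93 ± 0.811), AHR, the aryl hydrocarbon receptor (4.18 ± 0.652), SLC13A1 (2.85 ± 0.188) and OR7A10 (3.61 ± 0.255) rose on the strength of 1 probe each. The 2 h arrays differed widely for ELFN1 (13.29 ± 2.28) and AHR (12.52 ± 1.81; SD, n = 2 each). Over 19 alternative settings their changes ranged from 3.32 to 6.55 and from 2.90 to 5.46 log2, and the calls held in 12 and 13 of them. The largest falls were those of SLC33A2 (-2.27 ± 0.238), OR2M2 (-2.20 ± 0.295) and KRTAP10-4 (-2.20 ± 0.309), each with 1 probe. SIX5, RHOD, TRIM72, LENG1, FAM110D, CLEC4C and SLC49A3 followed, with falls from -1.56 to -1.21. Among these, TRIM72 had 2 of 2 probes over 1 log2 and the others, with 2 to 4 probes each, had 1.

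Of 25 cholesterol genes 3 rose at 2 h, among them INSIG1 by 1.32 ± 0.155 and DHCR7, a late reductase of cholesterol synthesis, by 0.82 log2. Adjusted over the list alone 5 rose, SQLE among them. The chaperones CALR, HSP90B1 and PDIA6 rose by 1.52, 1.22 and 0.95 (4 of 29 genes of their list adjusted over the list alone). EPCAM and CDH1, the adhesion molecule E-cadherin, rose by 2.14 ± 0.241 and 2.13 ± 0.368 (3 of 23 adjusted over the list alone). AGR2, MUC13 and MUC17 rose by 1.52, 1.09 and 1.33 (3 of 30 adjusted over the list alone). PARD6B, a polarity protein, was the 1 of 34 tight junction genes called, with 0.80 log2 (4 adjusted over the list alone). KRT20 rose by 1.32 ± 0.156 and FTH1 by 1.76 ± 0.133. PLAUR, the urokinase receptor, rose by 0.82, the 1 call of 41 immediate early genes (1 adjusted over the list alone). P4HA1 and GAPDH rose by 1.64 and 0.98 among 31 hypoxia and glycolysis genes (6 higher and 1 lower adjusted over the list alone). TSLP, an epithelial cytokine, fell by 0.73 log2 and ATP5MC3 by 1.08. Of the ribosomal protein genes RPL4, RPL39, RPS26 and RPS25 were higher and RPL35 was lower (16 higher and 2 lower of 76 adjusted over the list alone). Of 20 reference genes 3 were higher, among them ACTG1 and ACTB (7 higher and 1 lower adjusted over the list alone).

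Over all genes, limma called 156 higher and 45 lower at 2 h, with 1959 genes at an unadjusted p under 0.05. Of the 156 risen genes 155 had a 0 h mean below the 95th percentile of the negative control spots, as had nearly all human probes. Of the 188 called genes with 2 or more probes 123 had a single probe over 1 log2. With only the compared groups in the fit, 75 genes were called, so the pooled spread matters here as at 1 h. The 201 calls became 90 without 2 h replicate 1, 81 without 2 h replicate 2, 97 without either 4 h array, 66 with the median of a gene's probes, and 553 with 0 h replicate 1 and 1 h replicate 2 both left out, the last 2 settings being chosen after seeing the data.

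After 4 h the largest rises included cytoskeletal and glycolytic genes, several of which had also risen earlier. ACTB and ACTG1, the cytoplasmic actins, rose by 3.13 ± 0.261 and 2.37 ± 0.142 log2 (adjusted p = 0.00142 and 0.000197), and KRT18, a keratin of simple epithelia, by 2.08 ± 0.2, with all probes of these 3 genes over 1 log2. NDRG1, a hypoxia-responsive gene, rose from 8.43 ± 0.159 to 10.87 ± 0.117 (SD, n = 2 each), a change of 2.45 ± 0.148 (adjusted p = 0.000197). HSPA1A, the inducible HSP70, rose by 1.94 ± 0.136 (adjusted p = 0.000588, 1 probe). SCD (2.79 ± 0.282) was again among the largest rises, while OR7A10 (3.32 ± 0.255), TPD52L2 (2.38 ± 0.134), MUC17 (2.10 ± 0.22) and NRG3 (2.08 ± 0.18) rested on 1 probe over 1 log2. The largest falls were those of PITX3 (-1.80 ± 0.279) and MYO1A (-1.75 ± 0.254), followed by TMEM79, FAM110D, TMEM117, TMEM14A, PFN3, OR6C75, CCL19 and KCNG3. MYO1A, TMEM79 and TMEM117 had 2 of 3 probes over 1 log2. The other falls named here rested on 1 probe over 1 log2, of 2 or 3 probes.

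**Figure D2:**
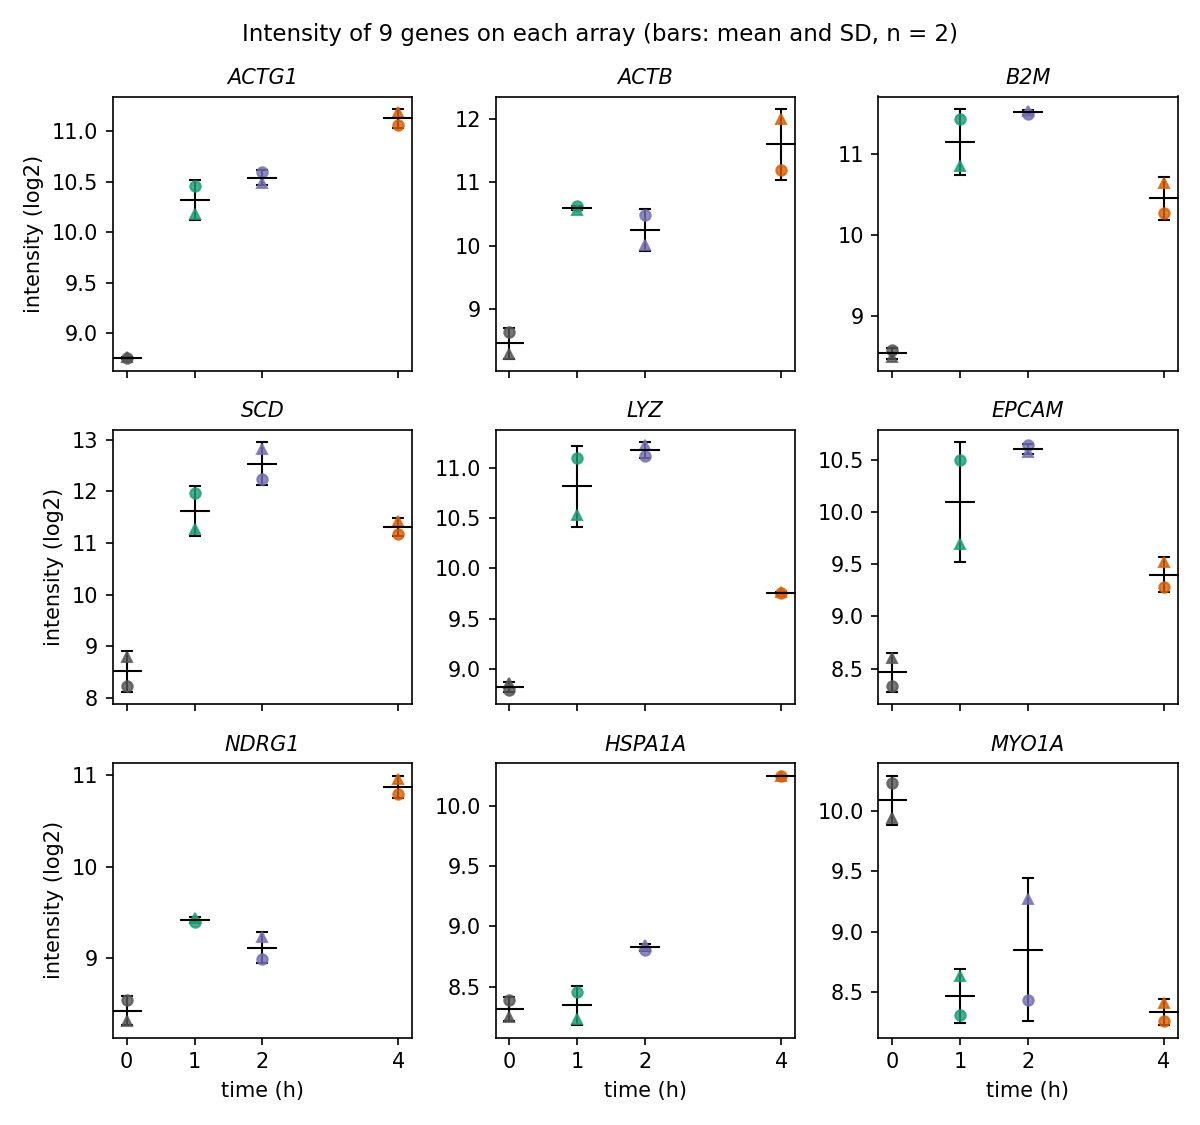
Log2 intensity (vertical axis) against time in h (horizontal axis) of 9 genes on the 8 arrays; circles are replicate 1, triangles replicate 2, and black bars the mean and SD of each pair. HSPA1A is near its 0 h level at 1 h and 1.94 log2 above it at 4 h, while SCD is highest at 2 h, 4.03 log2 above 0 h.

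The lists show which groups those genes came from at 4 h. Of 31 hypoxia and glycolysis genes 5 rose, NDRG1, GAPDH (1.90 ± 0.16), PDK1 (1.27), LDHA (1.10) and P4HA1 (1.03). Adjusted over the list alone 9 rose and 2 fell. LDHA changed sign to -1.80 log2 when only probes whose IDs end in S were used. Of 76 ribosomal protein genes 18 rose, led by RPL3 (2.05 ± 0.208) and RPLP1 (1.95), and 40 rose and 1 fell adjusted over the list alone. Of 20 reference genes 5 rose, among them EEF2, YWHAZ and the actins (8 rose and 1 fell adjusted over the list alone). Immediate early genes gave 4 calls of 41, DUSP1 (1.11 ± 0.121), FOS (1.09), MCL1 (0.93) and FOSL2 (0.81), and 5 adjusted over the list alone. FTH1 and FTL, the ferritin chains, rose by 1.73 and 1.70, 2 of 25 oxidative stress genes (3 higher and 1 lower adjusted over the list alone). HSPA8 rose by 1.20 beside HSPA1A, 2 of 36 heat shock genes (2 adjusted over the list alone). CLDN4 (1.02) was the 1 of 34 tight junction genes called, CALR (1.39) the 1 of 29 in the stress response list and DHCR7 (0.78) the 1 of 25 cholesterol genes (5, 5 and 4 adjusted over the list alone). MUC17 was the 1 of 30 mucin genes called (2 adjusted over the list alone), and LYZ, with 0.94 ± 0.183 log2, passed only adjusted over its list alone (adjusted p over all genes 0.0584). KRT20 and APOC3 rose by 1.54 and 0.86 and MYO1A fell among 36 enterocyte genes (3 higher and 1 lower adjusted over the list alone).

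Over all genes, limma called 156 higher and 12 lower at 4 h, with 2631 genes at an unadjusted p under 0.05. Of the 156 risen genes 155 had a 0 h mean below the 95th percentile of the negative control spots, as had nearly all human probes. Of the 151 called genes with 2 or more probes 81 had a single probe over 1 log2. The 168 calls became 66 without 4 h replicate 1, 28 without 4 h replicate 2, 97 with the median of a gene's probes, and 957 with 0 h replicate 1 and 1 h replicate 2 both left out, the last 2 settings being chosen after seeing the data.

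Immune signalling genes gave few calls at any time. Calls were rare in general, at 84, 201 and 168 of 18321 genes at 1, 2 and 4 h. The NF-kB and Toll-like lists had median log2 levels of 8.455 to 8.701, beside 8.415 to 8.683 for genes of unrelated tissues. Missing calls therefore do not show that these genes stayed unchanged. None of 29 genes of the NF-kB pathway passed limma's test at 1, 2 or 4 h, over all genes or adjusted over the list alone. At 4 h the members with the smallest p were RELB, with a log2 change of -0.69 (adjusted p = 0.112), and NFKB1, with 1.06 on 1 responding probe (adjusted p = 0.217). Among 32 NF-kB-driven cytokines and chemokines none rose, TSLP fell at 2 h, and CXCL3, a neutrophil chemokine, fell by 0.75 ± 0.133 log2 at 4 h (adjusted p = 0.0413; 2 lower adjusted over the list alone). Of 34 Toll-like and NOD-like receptor signalling genes IRAK4 (1.21 ± 0.147) and TRAF6 (1.92 ± 0.305) rose at 4 h, each with 1 probe over 1 log2. IRAK4 had risen at 2 h, also by 1.21. XAF1 (1.40 ± 0.249) was the 1 of 40 interferon-stimulated genes called at 4 h, and B2M (1.92 ± 0.203) the 1 of 25 antigen presentation genes. None of the 33 proliferation genes or 25 apoptosis and p53 target genes was called at 1, 2 or 4 h, over all genes or adjusted over the list alone. No leukocyte, fibroblast, endothelial or unrelated-tissue gene was called over all genes at those times; adjusted over the list alone the 1 exception was CD3D at 4 h, with a log2 change of 0.78.

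Tested as whole lists with camera at a preset correlation, 16 of the 75 combinations of list and time were shifted, each upward. Ribosomal protein genes had median changes of 0.29, 0.19 and 0.54 log2 at 1, 2 and 4 h (adjusted p = 5.18e-16, 6.65e-09 and 6.21e-27; adjusted p = 0.149, 0.22 and 0.149 with an estimated correlation), and reference genes 0.24, 0.16 and 0.39 (adjusted p = 4.96e-06, 0.000238 and 2.87e-08; adjusted p = 0.149 at each time with an estimated correlation). Cholesterol genes had medians of 0.11, 0.15 and 0.17 (adjusted p = 0.00386, 2.96e-05 and 0.000238; adjusted p = 0.22, 0.149 and 0.187 with an estimated correlation). Genes of the unfolded protein and stress response had 0.06, 0.09 and 0.06 (adjusted p = 0.0169, 0.00114 and 0.0312; adjusted p = 0.208, 0.149 and 0.22 with an estimated correlation). Hypoxia and glycolysis genes were shifted at 1 and 4 h, by 0.04 and 0.15 (adjusted p = 0.0383 and 4.38e-05; adjusted p = 0.221 and 0.149 with an estimated correlation). The oxidative stress list was shifted at 4 h, by 0.21 (adjusted p = 0.0175; adjusted p = 0.209 with an estimated correlation), and the adherens junction list at 1 h, by 0.07 (adjusted p = 0.0169; adjusted p = 0.221 with an estimated correlation). None of the 16 calls held with an estimated correlation, and the separation of the ribosomal and reference genes from unrelated-tissue genes differed between the same arrays, as given above. So did the ratio of a pair of control spots named for the 3' and 5' end, at 1.17 and 1.07 at 0 h and 1.55 to 2.48 on the inoculated arrays, looked at after seeing the data.

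**Figure D3:**
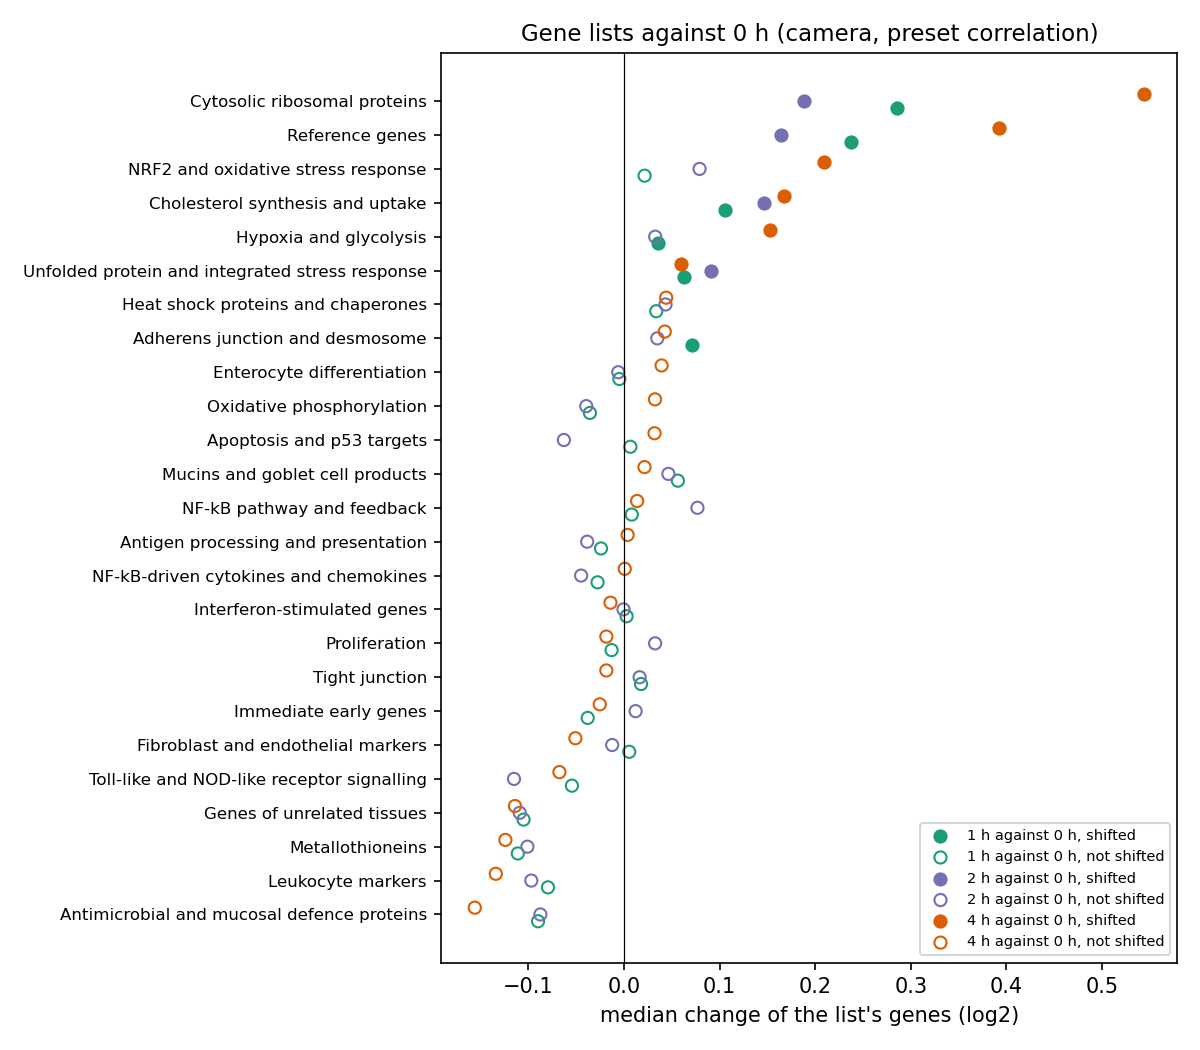
Median log2 change (horizontal axis) of the 25 gene lists (vertical axis) at 1, 2 and 4 h against 0 h; filled circles are lists shifted by camera with the preset correlation and open circles lists that were not. Ribosomal protein genes have the largest median at each time, 0.54 at 4 h, and none of the filled circles lies below 0.

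Averaged over 1, 2 and 4 h, the largest rises among genes with more than 1 responding probe included those of SCD (3.31 ± 0.231), B2M (2.50 ± 0.166), ACTB (2.35 ± 0.213) and TM4SF4 (2.18 ± 0.325). The largest falls were those of SLC33A2 (-1.76 ± 0.194), KRTAP10-4 (-1.67 ± 0.253), MYO1A (-1.53 ± 0.207) and PITX3 (-1.42 ± 0.228). G0S2, LENG1, SRD5A2, TMEM14A, ADTRP and FAM110D fell by smaller amounts. Of these falls, those of MYO1A and SRD5A2 had 2 probes over 1 log2, and the others had 1. In this contrast limma called 228 genes higher and 62 lower, with 2544 at an unadjusted p under 0.05. Without 0 h replicate 1 the balance was 205 higher and 184 lower. Higher in each of the 3 comparisons were 43 genes, and 2 were lower in each. The comparisons share their 0 h arrays. Of the risen genes 69 were shared by 1 and 2 h, 47 by 1 and 4 h and 64 by 2 and 4 h. Independent lists would share 0.656, 0.656 and 1.33. Simulated arrays with no effect shared 0.1, 0.05 and 0.05 calls of either direction. With no effect few genes are called at all, so the simulated counts cannot show how much sharing the common 0 h arrays produce. Fold changes across genes correlated at r = 0.841, 0.707 and 0.719, against 0.501, 0.497 and 0.499 for simulated arrays with no effect, and their covariances were 0.0664, 0.0587 and 0.0684 against 0.0167, 0.0166 and 0.0167. Genes are not independent replicates, and a split of the 2 control arrays would leave 1 per comparison. The simulated arrays also held no effect shared across an array, so part or all of the excess may come from the shared controls. The 290 calls became 167 without 2 h replicate 1, 124 and 94 without 4 h replicate 1 and 2, 107 with the median of a gene's probes, and 906 with 0 h replicate 1 and 1 h replicate 2 both left out, the last 2 settings being chosen after seeing the data.

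Between inoculated groups, with no 0 h array in the contrast, 6 genes were higher at 4 h than at 1 h and none was lower. HSPA1A rose from 8.34 ± 0.162 to 10.25 ± 0.000602 (SD, n = 2 each), by 1.91 ± 0.136 log2 (adjusted p = 0.0033). NDRG1 rose by 1.46 ± 0.148 (adjusted p = 0.0174) with all 3 of its probes over 1 log2. NRG3 (2.15 ± 0.18), MCMBP (1.42 ± 0.139) and APOC3 (1.37 ± 0.161) rose on 1 probe over 1 log2 each, and the histone gene H2BC4 (1.59 ± 0.189) has 1 probe. Adjusted over the list alone, DUSP1, FOSL2 and ZFP36L1 were higher among 41 immediate early genes, GAPDH, NDRG1 and PKM among 31 hypoxia and glycolysis genes, and 9 of 76 ribosomal protein genes, while LYZ was lower by 1.05 ± 0.183 log2 among 34 antimicrobial genes. limma gave 1092 genes at an unadjusted p under 0.05 where 916.05 are expected by chance. The balance depended on single arrays: the 6 calls became 16 (8 higher and 8 lower) without 1 h replicate 1, 11 (7 and 4) without 1 h replicate 2 and 9 (4 and 5) without 4 h replicate 2. They became 10 without either 2 h array, 24 (17 and 7) with only the compared groups in the fit, 2 with the median of a gene's probes, and 30 with 0 h replicate 1 and 1 h replicate 2 both left out.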

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

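All tests of explanations in this part were chosen after the results were seen, as were the comparisons of 4 h with 2 h and of 2 h with 1 h and the list tests between inoculated groups.

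Abundant human transcripts lay near background on both 0 h arrays. Quantile normalization between arrays keeps the ranks within an array, yet the upper 95% bound of ribosomal separation on a 0 h array reached at most 0.627, below the lowest inoculated value of 0.732, which argues against it. A candidate explanation is little labelled human RNA on the 0 h arrays: of 95 ribosomal protein and reference genes at most 5.26% lay above the 95th percentile of unrelated-tissue genes on a 0 h array, against 47.4% and 63.2% at 4 h, although 1 h replicate 2 and 2 h replicate 2 had 6.32%. A rise of these transcripts in the cells after contact stays open as the biological explanation: mean separation at 4 h was 0.848, and because uninoculated arrays exist only at 0 h the 2 explanations cannot be told apart. Every comparison with 0 h rests on these arrays; those between inoculated groups take no mean from them but share their spread, and the share above differed there too, with 22.1% and 6.32% at 1 h.

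Many called genes had a single responding probe. In the 81 such genes at 4 h the 148 other probes had a median change of 0.27 log2 and an upper quartile of 0.54 (0.541). The responding probes had a median of 2.29. Probes were split at 1 log2 in these same data, so the gap follows in part from the selection. Whether other RNA hybridized to the responding probe stays undecided. Probes that respond poorly to their own transcript are a candidate explanation for part of these genes, since 36.4% of the 22 called ribosomal protein and reference genes with 2 or more probes showed the same split. That share is smaller than the 81 of 151 among all called genes with 2 or more probes at 4 h. The design gives no biological explanation to test here, and probe sequences, which would bear on bacterial RNA, were not used.

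The array of 0 h replicate 1 resembled 1 h replicate 2 (Spearman's rho over all probes 0.787, across probes, which are not independent) more than its own replicate (0.192). The ribosomal separation of 0.732 on 1 h replicate 2 lay above the upper 95% bound of 0.585 on 0 h replicate 2, which argues against exchanged labels. That reading takes low separation to mark 0 h arrays, which may be technical. The share of abundant genes above background was 6.32% on 1 h replicate 2, near the 4.21% and 5.26% at 0 h. It was 22.1% on 1 h replicate 1 and 6.32% on 2 h replicate 2. Exchanged labels are therefore not excluded. A background pattern of dim probes shared by these arrays is a candidate explanation: over genes below the median mean, rho was 0.7 for this pair and at most 0.426 for any pair of replicates. This pair does not stand alone, since 1 h replicate 1 and 2 h replicate 1 had 0.663 (0.827 over all probes). No biological explanation was tested.

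Genes that differed between times of contact were flagged by the test of that difference. At 4 h against 1 h the log2 changes were 1.91 for HSPA1A, 2.15 for NRG3 (2.155), 1.42 for MCMBP, 1.46 for NDRG1, 1.37 for APOC3 and 1.59 for H2BC4. At 4 h against 2 h they were 2.20 for NRG3, 1.76 for NDRG1, 1.43 for HSPA1A, 1.35 for MCMBP, 1.06 for VHLL and -1.56 for SLC13A1.

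Lists were flagged likewise by camera at the preset correlation. Median log2 changes at 4 h against 1 h were 0.0795 for immediate early genes (adjusted p = 0.00232), 0.10 for hypoxia and glycolysis (adjusted p = 0.000214), 0.24 for ribosomal proteins (adjusted p = 1.24e-12) and 0.25 (0.245) for reference genes (adjusted p = 0.000174). At 4 h against 2 h the medians of those lists were 0.0537, 0.12, 0.27 and 0.17 (adjusted p = 0.0279, 0.000364, 3.54e-18 and 5.69e-05). At 2 h against 1 h they were 0.0835 for the unfolded protein and stress response (adjusted p = 0.0488) and 0.0886 for cholesterol genes (adjusted p = 0.00523). With an estimated correlation none of these list calls held, with adjusted p from 0.113 upward.

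Among the 114 control spots, which the comparisons do not use, at least 10 were brighter on all 6 inoculated arrays than on both 0 h arrays. That count leaves out spots whose margin was lost in rounding (lowest inoculated 369.33 against highest 0 h 368.48, and 346.23 against 345.35). Dimmer on all 6 were 15, where chance gives 4.07 in either direction. In 2 of the brighter spots the lowest inoculated intensity was at least 2-fold the highest 0 h intensity: 8.33-fold for a control spot outside the negative controls and 2.31-fold for a negative control named for a phage. A negative control named for bacteria went the other way, with its lowest 0 h intensity 2.98-fold the highest inoculated one. A pair of control spots named for the 3' and 5' end had intensity ratios of 1.17 and 1.07 on the 0 h arrays and 1.55 to 2.48 on the inoculated arrays. What these spots measure is not given in the sources used here, and the ratio was looked at after seeing the data.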

How the results depend on the processing

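All gene counts depend on processing; the alternatives named as added were chosen after seeing the data, and except where stated the cause was not tested. In the order 1, 2 and 4 h against 0 h and mean of the 3 times, a variance prior with trend and robust gave 38, 104, 108 and 175 genes, and the median of probes (added) 29, 66, 97 and 107, plus 2 for 4 h against 1 h and 2 for 4 h against 2 h. A fit per probe, which counts probes, gave 156, 343 and 459 at 1 h, 2 h and the mean. Only the compared groups in the fit gave 15 and 75 at 1 and 2 h, and 24 and 67 for 4 h against 1 h and 2 h. The SD of the log2 difference between replicates fell from 0.371 at 0 h to 0.305, 0.251 and 0.224 at 1, 2 and 4 h. The main fit pools these spreads, so comparisons with 0 h at 1 and 2 h borrow the narrower spread of 4 h. Those of 4 h with 1 h and 2 h carry the wider spread of 0 h. Whether this accounts for the counts was not tested. A fold of at least 2 asked for besides adjusted p gave 132 at 2 h and 115 for the mean, by construction fewer, and asked for with an unadjusted p under 0.001 instead gave 116 for the mean, 21 for 4 h against 1 h and 32 for 4 h against 2 h. Probes with IDs ending in S (added) gave 129, 97 and 175 at 2 h, 4 h and the mean, and 3 for 4 h against 2 h. Leaving out 0 h replicate 1 and 1 h replicate 2 together (added) gave 291, 553, 957 and 906, with 57.4%, 55%, 52.6% and 51.5% higher, and 30 and 67 for 4 h against 1 h and 2 h. The replicate numbers were not taken to pair the samples (correlations of replicate deviations between groups ran from -0.422 for 0 and 1 h to 0.394 for 1 and 2 h); the replicate block gave 54, 132 and 100 genes at 1, 2 and 4 h and 2 for 4 h against 1 h. Without each array in turn, a lone array taken to vary like the other groups, the shares higher without 0 h replicate 1 were 56.2%, 62%, 65.1% and 52.7% at 1, 2 and 4 h and for the mean, and the counts ran from 40 to 162 at 1 h, 81 to 240 at 2 h, 28 to 252 at 4 h, 94 to 427 for the mean, 5 to 16 for 4 h against 1 h and 7 to 16 for 4 h against 2 h (14 and 16 without 2 h replicate 1 and 2). List calls against 0 h ran from 11 to 19, those of 4 h against 1 h and 2 h from 3 to 5 each, and those of 2 h against 1 h from 0 (without 2 h replicate 1) to 3, with 1 without either 0 h array or 1 h replicate 1. An estimated correlation gave 0 list calls in each set of comparisons, genes above the median mean and probes with IDs ending in S 10 each against 0 h. Against 0 h fry gave 18 list calls, 17 upward. For 2 h against 1 h fry gave 0 list calls, and the compared groups alone, the variance prior, probes ending in S, the median of probes and the omission of both arrays gave 1 each, downward in the last case. Quantile normalization, median centring, an offset of 50 and zeros as missing (added) kept the 5 counts of the report and the list calls against 0 h within 1.5 times. Because 7 of the 8 arrays already hold the same sorted intensities, quantile normalization and median centring could change little besides 4 h replicate 2. Zeros concern only 12 or 5 spots per array. The agreement under these settings is therefore no check of the normalization. For 4 h against 2 h quantile normalization gave 4 genes, 100% higher, against 6 with 83.3% higher. Of 3780 values of the 201 called gene results under the alternatives, 2924 kept their call, 854 lost it and 2 changed sign: LDHA at 4 h to -1.80 with probes ending in S and OR6C75 at 4 h to 0.14 with the median of probes. Among genes not called, with the median of probes SDHD (0.19) and TSLP (0.19) at 1 h, HLA-DMA (-0.01048), MS4A1 (0.005327), NFKB1 (-0.07633) and TSLP (0.33) at 4 h and HPRT1 (-0.20) for 4 h against 1 h changed sign, as did RPL6 (-0.02044) at 4 h with probes ending in S. Signal over background limits every comparison with 0 h.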

Other observations

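The genes of the first paragraph, and all results of 4 h against 2 h and of 2 h against 1 h, were chosen after seeing the data. Of the 43 genes higher at each of 1, 2 and 4 h, 18 had at least 2 probes over 1 log2 at each time. Besides genes already named, they include surface and secretory pathway genes. CD63 and TSPAN8, tetraspanins, rose by 2.27 ± 0.159 and 2.08 ± 0.209 log2 at 2 h and by 1.19 ± 0.159 and 1.23 ± 0.209 at 4 h. CD164, a sialomucin, rose by 1.64, 1.68 and 1.35 at 1, 2 and 4 h, ITGB1, the integrin beta-1 chain, by 1.24, 1.43 and 1.08, and KDELR1, a receptor that returns proteins to the endoplasmic reticulum, by 1.85, 1.83 and 1.21. PTPRF, TXNIP, an inhibitor of thioredoxin, and the transcription factor PITX1 were also among them.

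Between 2 h and 4 h of contact, a contrast that leaves out the 0 h arrays, limma called 5 genes higher and 1 lower, with 1117 genes at an unadjusted p under 0.05 where 916.05 are expected. Without 4 h replicate 2 the calls were 2 higher and 5 lower, and with only the compared groups in the fit 45 and 22. NDRG1 rose from 9.11 ± 0.168 to 10.87 ± 0.117 (SD, n = 2 each; adjusted p = 0.00694) and HSPA1A from 8.82 ± 0.0305 to 10.25 ± 0.000602 (adjusted p = 0.0134), while SLC13A1 fell from 11.23 ± 0.039 to 9.68 ± 0.211 (adjusted p = 0.0485). LYZ had a change of -1.41 ± 0.183 (adjusted p = 0.0645) and CD63 one of -1.09 ± 0.159 (adjusted p = 0.0986), neither past the threshold. Of 31 hypoxia and glycolysis genes 4 were higher and 1 lower adjusted over the list alone, and of 76 ribosomal protein genes 13 were higher. Between 1 h and 2 h limma called 0 genes, with 195 at an unadjusted p under 0.05, far below the 916.05 expected. Replicate deviations correlated at 0.394 across genes between these 2 groups, which the unpaired fit does not model. The 0 calls therefore do not show that no gene changed between 1 h and 2 h.

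The remaining lists showed no shift by camera at 4 h. Metallothioneins had median changes of -0.11, -0.10 and -0.12 log2, with SLC30A1, a zinc exporter, higher adjusted over the list alone at 2 h and 4 h (0.70 and 0.60) and MT1B lower at 2 h (-0.55). Antimicrobial genes had medians of -0.09, -0.09 and -0.16. Oxidative phosphorylation genes had -0.04, -0.04 and 0.03, mucins 0.06, 0.05 and 0.02, tight junction genes 0.02, 0.02 and -0.02 and interferon-stimulated genes 0.00277, -0.000435 and -0.01. At 4 h camera gave adjusted p = 0.0547 for heat shock proteins, 0.0762 for immediate early genes, 0.111 for adherens junction genes and 0.179 for enterocyte genes. It gave 0.706 for NF-kB-driven cytokines, which fry called lower (adjusted p = 0.0358, the 1 downward list among its 18 calls), 0.988 for the NF-kB pathway, 0.788 for Toll-like and NOD-like receptor signalling, 0.514 for antigen presentation, 0.958 for proliferation and 0.788 for apoptosis and p53 targets. For leukocyte, fibroblast and endothelial, and unrelated-tissue genes it gave 0.369, 0.495 and 0.115. At 2 h the hypoxia and oxidative stress lists had adjusted p = 0.0961 and 0.0613.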
